A study of Homo sapiens with 42 samples.

How the data were processed

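Messenger RNA was measured on 42 one-colour Affymetrix arrays, each hybridised with biotin-labelled target made from 100 ng of total RNA. The labels name 2 cell lines, H460 and H1299, with 6 arrays each at 0 h and 3 each at 2, 4, 8, 12 and 24 h after 2 Gy, and call the arrays of a group biological replicates. This gives 12 groups, all of which were used. The deposited values are log2 array summaries that the authors normalized by a method the labels do not state. They run from 1.45 to 14.2, and the array medians of the genes tested lay between 5.97 and 6.18. The values came without detection calls, so no level of background was set. No pair of arrays was identical (0 pairs).

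The table had 32321 rows. Of these, 19158 had 1 gene symbol, 1388 had several and 11775 were outside the probe table. Entries with 1 symbol were used, and where a gene had several the one with the highest mean over all arrays was kept, which left out 754. The gene table held 19128 of the symbols. In all, 18404 genes were tested, without a filter on dim genes. Some genes are not analysed here.

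Each line's time course was tested by quadratic regression on hours (limma 3.58.1 in R 4.3.3, lmFit and eBayes with trend), as a moderated F-test of both time coefficients over the 21 arrays of the line. Changes at each time point were contrasts against 0 h in a model with 1 mean per time point over the same 21 arrays. The difference between the lines was the interaction of line with time over all 42 arrays, and at each time point the H460 change minus the H1299 change. The lines before irradiation were compared over the 12 arrays at 0 h. All tests were two-sided. Adjusted p is by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. Errors after ± are model standard errors. The smallest changes that can be told from 0 follow from 3 arrays per time point, and the number of arrays limits the precision.

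The 20 gene lists were written before the data were examined: p53 targets, G2/M genes, G1/S and replication genes, replication-dependent histones, double-strand break repair, DNA damage checkpoint, NF-kB targets, interferon-stimulated genes, immediate-early genes, BCL2 family and caspases, NRF2 targets, epithelial genes, mesenchymal genes, ATF4 targets, hypoxia genes, cholesterol synthesis, circadian clock genes, cytosolic ribosomal proteins, fibroblast markers and leukocyte markers. They hold 637 genes, of which 588 were measured. A list was tested with camera (limma) against all other genes with a preset correlation of 0.01 between genes, adjusted over all lists and time points of a line, of the difference, or of 0 h. Beside it the correlation was estimated from the data, and members were counted at adjusted p under 0.05 over all genes and over the list alone.

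The comparisons, the lists, the other settings and the rule for naming genes were fixed before the data were examined. By the rule, CDKN1A and MDM2 are always named. For each line's time course, for the difference and for 0 h, the 10 genes with the largest rise and the 10 with the largest fall are named among called genes whose arrays do not overlap those at 0 h (for the difference in at least 1 line, for 0 h between the lines). For each list up to 4 members with the smallest p may be named. MicroRNA and unnamed loci may stay unnamed.

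Other settings chosen before the data were examined were a filter leaving out the 33.3% of genes with the lowest highest group mean, all entries of the table, eBayes without trend, robust eBayes, quantile normalization, centring each array on its median, array weights, a block for the replicate number, all 42 arrays or only those of the 2 time points compared, 0 h replicates 1 to 3 or 4 to 6 only, 1 mean per time point, the square root of hours, the rank of the time point, the 24 h arrays left out, camera on ranks, an estimated correlation, and each array left out in turn. Chosen after seeing the data were the interquartile range of each array (array width or spread) as a covariate, 4 arrays of narrow spread left out (H460 at 2 h and H1299 0 h replicate 2), and the list tests after quantile normalization or median centring.

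Comparisons were tested on simulated data, with 100 of 18404 genes changed by 0.5 and 100 by 1 (log2). For a change of 1 the test recovered 99 of 100 for the H460 time course, 99 for H460 at 4 h, 100 for the H1299 time course, 99 for H1299 at 8 h, 98 for the difference of time courses, 89 for the difference at 8 h and 99 at 0 h. For a change of 0.5 it recovered 76, 57, 75, 56, 39, 22 and 74. All signs were right, but only 37 of 39 for the difference of time courses. False calls were 1.9% to 7.14% of calls. Rates on real arrays, of unequal spread, were not tested.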

Results

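The data were mRNA levels in 2 human lung cancer cell lines, H460, a large-cell carcinoma line named as radiosensitive by the study, and H1299, a non-small cell carcinoma line named as radioresistant. Exponentially growing cells received 2 Gy of gamma radiation. Each line had 6 arrays before irradiation (0 h) and 3 arrays at each of 2, 4, 8, 12 and 24 h, which makes 42 arrays with 21 per line. Levels are log2 intensities, and 18404 genes were tested. Changes are log2 differences from 0 h of the same line with the standard error of the model (3 arrays against 6). No array is labelled as unirradiated after 0 h, so time since irradiation and time in culture run together in every change. The protocol speaks of control cells kept for the same times, and whether any array labelled 0 h held such cells could not be told. If so, the 0 h mean would mix times in culture. Gene lists were tested with a preset correlation of 0.01 between genes. Counts marked "list alone" have p adjusted within the list. A list call with the fixed settings also held with a correlation estimated from the data unless a second adjusted p is given. Calls with other settings were not tested that way.

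The width of the array distributions differed between groups. The mean interquartile range was 2.84 at 2 h in H460 (SD 0.117, n = 3), against 3.34 at 0 h (SD 0.169, n = 6) and 3.64 at 8 h (SD 0.0213, n = 3). In H1299 it was 3.58 at 0 h (SD 0.173, n = 6), 3.53 at 2 h (SD 0.102, n = 3) and 3.82 at 12 h (SD 0.0997, n = 3). The first principal component held 53% of the variance in H460 and 34.3% in H1299, and its absolute correlation with the interquartile range over the 21 arrays of each line was 0.989 and 0.926. Across genes, which are not independent replicates, the change at 2 h in H460 had r = -0.73 with the slope of each gene on array width within groups. That correlation was 0.68 at 8 h, 0.61 at 12 h and 0.54 at 24 h in H460, and 0.55 at 8 h and 0.56 at 12 h in H1299.

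**Figure D1:**
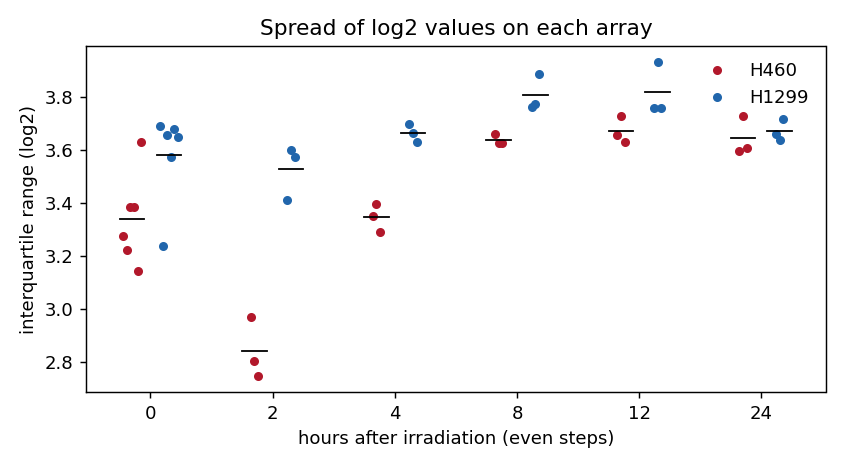
Interquartile range (log2 units, y axis) of each of the 42 arrays by hours after irradiation (x axis) for H460 and H1299. Points are arrays and black bars are group means. The 3 H460 arrays at 2 h lie between 2.75 and 2.97, below every other H460 array.

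The H460 time course asks which genes responded to 2 Gy in the radiosensitive line. Targets of the p53 protein rose from 4 h on. CDKN1A (row 8119088), which encodes the cell cycle inhibitor p21, rose by 1.62 ± 0.13 at 4 h (3.07-fold, adjusted p = 1.06e-08). MDM2 (row 7956989), the ubiquitin ligase that degrades p53, rose by 1.12 ± 0.11 at 4 h (2.17-fold, adjusted p = 3.23e-07). TP53INP1 rose by 1.91 ± 0.12, SPATA18 by 1.51 ± 0.15 and the receptor gene EDA2R by 1.34 ± 0.11 at 12 h, and cyclin G1 (CCNG1) by 0.99 ± 0.12 at 24 h. Of the 44 measured p53 targets, at 4 h 26 rose and 0 fell (35 and 2, list alone), with a median change of 0.52 (adjusted p = 5.17e-44). At 8 h 32 rose and 0 fell (33 and 0, list alone), with a median change of 0.61 (adjusted p = 5.41e-24). At 12 h 30 rose and 1 fell (32 and 1, list alone), with a median change of 0.60 (adjusted p = 2.24e-16). At 24 h 27 rose and 0 fell (28 and 2, list alone), with a median change of 0.45 (adjusted p = 5.11e-10). At 2 h 10 rose and 4 fell (10 and 4, list alone) and the list did not pass the test, with a median of 0.12 (adjusted p = 0.0694). That 2 h median was 0.22 (adjusted p = 2.9e-07) with array width in the model and 0.30 (adjusted p = 0.000102) after quantile normalization. It was 0.17 (adjusted p = 0.000346) without dim genes and 0.11 (adjusted p = 0.0452) with a replicate block. Without 0 h replicate 6 or 2 h replicate 3 it was 0.10 (adjusted p = 0.0325) and 0.15 (adjusted p = 0.00735).

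**Figure D2:**
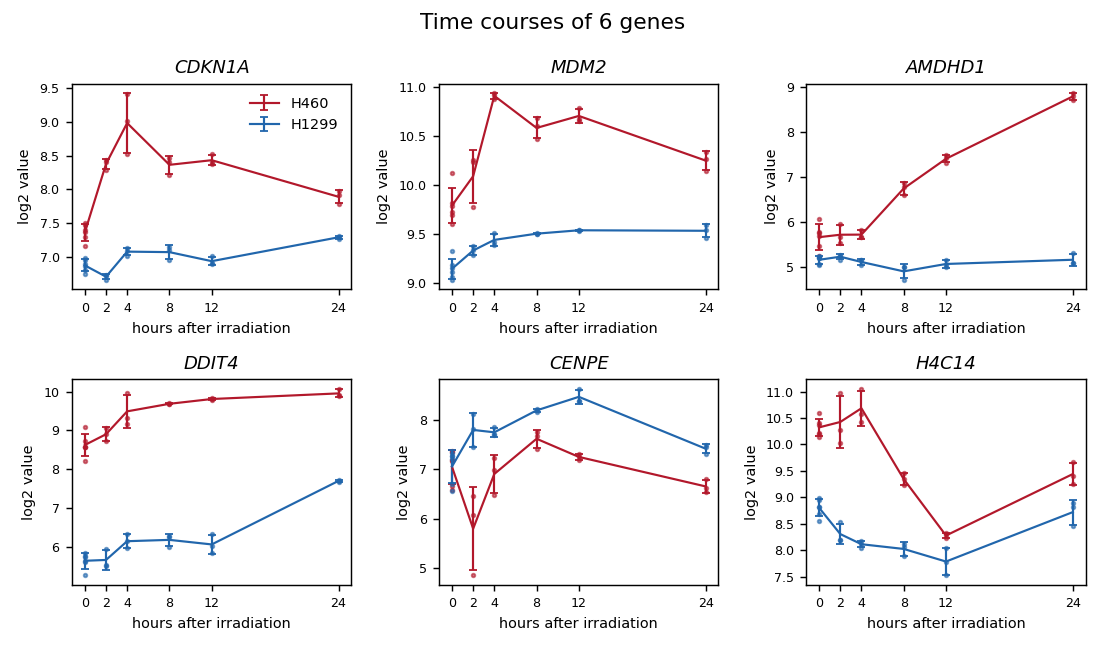
Levels (log2 intensity, y axis) of CDKN1A, MDM2, AMDHD1, DDIT4, CENPE and H4C14 by hours after irradiation (x axis) in both lines. Points are arrays, lines join group means and bars are SD. In H460 AMDHD1 at 24 h and CDKN1A at 4 h lie above all 0 h arrays, by 3.12 and 1.62 on average.

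The largest rises in H460 were all at 24 h, with arrays not overlapping those at 0 h, as the naming rule required. AMDHD1 (row 7957654), an enzyme of histidine breakdown, rose by 3.12 ± 0.14 (8.67-fold, adjusted p = 2.46e-14). PDK4, a kinase that inhibits pyruvate dehydrogenase, rose by 2.71 ± 0.13, PLAC4 by 2.61 ± 0.14, the succinate receptor SUCNR1 by 2.58 ± 0.19 and the transporter ABCA8 by 2.42 ± 0.19. CTH, which makes cysteine from cystathionine, rose by 2.32 ± 0.14, SERPINB11 by 2.30 ± 0.19, the monocarboxylate transporter family gene SLC16A4 by 2.29 ± 0.14, VWA5A by 2.26 ± 0.13 and the carboxypeptidase inhibitor LXN by 2.14 ± 0.22. SUCNR1 stood at 2.98 at 0 h, and values had no detection call, so part of such a fold rests on a level with no measured floor.

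The largest falls in H460 were led by replication-dependent histones at 12 h. The log2 changes were -2.05 ± 0.15 for H4C14 (adjusted p = 1.21e-09), -1.94 ± 0.14 for H2AC21, -1.82 ± 0.15 for H3C2, -1.72 ± 0.12 for H4C2, -1.70 ± 0.12 for H2BC14 and -1.67 ± 0.16 for the linker histone H1-5. Cyclin E2 (CCNE2), which drives entry into S phase, fell by 1.79 ± 0.15 at 8 h. The collagenase MMP1 fell by 1.76 ± 0.14 at 24 h. The AP-1 subunit JUN fell by 1.73 ± 0.13 and the skin adhesion gene CDSN fell by 1.71 ± 0.34 at 12 h. Of the 43 measured replication-dependent histones, at 12 h 0 rose and 35 fell (1 and 35, list alone), with a median change of -0.81 (adjusted p = 6.41e-21, but adjusted p = 0.096 with estimated correlation). H4C1 fell by 1.55 ± 0.17 at 12 h. At 24 h 3 rose and 10 fell (3 and 11, list alone), and the list did not pass the test, with a median of -0.10 (adjusted p = 0.132), against -0.31 (adjusted p = 0.000223) with array width in the model. Histone genes have near-identical copies, so which copy a probe set measured is uncertain. With array width in the model the time courses of H2BC14, H1-5 and CDSN no longer passed, with adjusted p = 0.121, 0.0504 and 0.222, while their 12 h changes were -1.89, -2.23 and -1.13. With the square root of hours those of H2AC21, H3C2, H2BC14, H1-5 and CDSN did not pass (adjusted p = 0.0681, 0.0666, 0.112, 0.286 and 0.222). Without 12 h replicate 1, 2 or 3 the adjusted p for H1-5 was 0.101, 0.0989 or 0.101, and with a replicate block it was 0.0581. Without replicate 1 or 2 that for CDSN was 0.0642 or 0.0982. With ranks of time the adjusted p for H1-5 and CDSN was 0.212 and 0.1.

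Genes of the cell cycle moved in a time-dependent way in H460. Of the 43 measured genes of G2 and mitosis, at 8 h 19 rose and 0 fell (29 and 0, list alone). The list median was 0.36 (adjusted p = 2.12e-11, but 0.189 with estimated correlation). At 24 h 0 rose and 33 fell (0 and 34, list alone). The median was -0.46 (adjusted p = 3.25e-14, but 0.139 with estimated correlation). At 24 h CDC20, an activator of the anaphase-promoting complex, fell by 0.91 ± 0.092. UBE2C, a ubiquitin-conjugating enzyme of that complex, fell by 0.73 ± 0.10 and cyclin A2 (CCNA2) fell by 0.81 ± 0.10. Of the 43 measured genes of G1/S and replication, at 12 h 0 rose and 28 fell (0 and 28, list alone). The list median was -0.46 (adjusted p = 2.51e-11, but 0.172 with estimated correlation). At 24 h 0 rose and 29 fell (0 and 31, list alone). The median was -0.47 (adjusted p = 3.54e-13, but 0.139 with estimated correlation). The replication helicase subunit MCM5 fell by 0.79 ± 0.084 at 24 h and the uracil glycosylase UNG fell by 0.98 ± 0.11 at 8 h. At 2 h, when the arrays were narrow, 34 of the G2 and mitosis genes fell and 0 rose (34 and 0, list alone). The list median was -0.47 (adjusted p = 5.07e-09, but 0.265 with estimated correlation). With array width in the model that median was -0.050 (adjusted p = 0.243), though at 2 h this term cannot separate time from width. The same term left the G1/S list at 2 h at 0.0013 (adjusted p = 0.385), against -0.33 without it (adjusted p = 4.79e-06, but adjusted p = 0.37 with estimated correlation). It left the 12 h median of the G2 and mitosis list at -0.26 (adjusted p = 1.75e-06), against -0.025 (adjusted p = 0.726).

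Metabolic and stress groups rose in H460 at the later times. Of the 22 measured genes of cholesterol synthesis, at 8 h 16 rose and 0 fell (18 and 0, list alone), with a median change of 0.55 (adjusted p = 7.8e-13). At 12 h 20 rose and 0 fell (20 and 0, list alone), with a median change of 0.55 (adjusted p = 1.34e-11). At 24 h 19 rose and 0 fell (19 and 0, list alone), with a median change of 0.50 (adjusted p = 5.53e-13). The fatty acid desaturases FADS2 and SCD rose by 1.53 ± 0.093 and 1.48 ± 0.084 at 24 h, the sterol transporter STARD4 by 1.26 ± 0.12 and the last enzyme of the pathway, DHCR7, by 0.93 ± 0.090. Of the 27 measured NRF2 targets, at 24 h 15 rose and 2 fell (17 and 2, list alone), with a median change of 0.35 (adjusted p = 3.13e-06, but adjusted p = 0.144 with estimated correlation), and the exporter ABCC3 rose by 1.18 ± 0.10. Of the 30 measured ATF4 targets, at 24 h 16 rose and 1 fell (19 and 1, list alone), with a median change of 0.34 (adjusted p = 2.04e-06, but adjusted p = 0.0795 with estimated correlation). The mTORC1 inhibitor SESN2, also a p53 target, rose by 0.87 ± 0.11 at 12 h.

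Of the 37 measured interferon-stimulated genes in H460, at 24 h 19 rose and 1 fell (19 and 1, list alone), with a median change of 0.36 (adjusted p = 1.11e-05, but adjusted p = 0.0743 with estimated correlation). The antiviral gene OAS1 rose by 0.81 ± 0.10 at 24 h. The NF-kB target genes IL6, CCL20 and IL1A encode inflammatory mediators. IL6 rose by 1.44 ± 0.14, CCL20 by 1.39 ± 0.21 and IL1A by 1.29 ± 0.18 at 24 h. Of the 25 measured NF-kB targets, 8 rose and 4 fell (10 and 4, list alone), with a median change of 0.070 (adjusted p = 0.0482, but adjusted p = 0.385 with estimated correlation), and the median was -0.0081 (adjusted p = 0.292) with array width in the model. Leaving out 1 array, that call ended with adjusted p = 0.0586, 0.0544 and 0.0606 without H460 0 h replicates 1, 4 and 5, 0.0548 and 0.0527 without H460 2 h replicates 1 and 3, 0.0527, 0.0555 and 0.0502 without H460 4 h replicates 1, 2 and 3, 0.0516 without H460 12 h replicate 2, 0.0732 and 0.0727 without H460 24 h replicates 2 and 3. The initiator caspase CASP9 rose by 1.06 ± 0.11 at 24 h, while the 28 measured BCL2 family and caspase genes had a median of -0.041 and did not pass the test (adjusted p = 0.727), with 7 members up and 5 down (7 and 7, list alone).

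In all, 7712 genes had a time course in H460 by the quadratic regression (limma, 3779 with a rise and 3933 with a fall as their largest change), of which 306 rose and 74 fell by at least 2-fold. Against 0 h, 7435 genes changed at 2 h (3071 higher, 4364 lower), 538 at 4 h (252 and 286, but 305 higher and 192 lower after quantile normalization and 466 higher and 138 lower after median centring). At 8 h 3108 changed (1963 higher, 1145 lower), at 12 h 6161 (3065 and 3096), and at 24 h 5275 (2988 and 2287, but 2602 higher and 3152 lower after median centring). With 1 mean per time point 12752 genes had a time course. With array width in the model, a term chosen after the widths were seen, 2912 genes had a time course, and 977, 132, 628 and 1548 genes changed at 4, 8, 12 and 24 h. At 2 h that limma fit called 0 genes and limma's robust fit also 0, with 1528 at an unadjusted p under 0.05 (9039 without the term). Without 1 array the 2 h count was 4349 (2 h replicate 3), the 4 h count 138, 179 or 845 (4 h replicates 3 and 1, 0 h replicate 6). The 8 h count was 1071, 1222, 1457 or 4939 (8 h replicates 1, 2 and 3, 0 h replicate 6). Likewise the 12 h count was 3816 or 4001 (12 h replicates 2 and 3) and the 24 h count 2820 (24 h replicate 2).

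The H1299 time course asks the same of the radioresistant line. DDIT4 (row 7928308), an inhibitor of mTORC1 signalling, rose the most, by 2.06 ± 0.13 at 24 h (4.17-fold, adjusted p = 4.44e-11). BLID rose by 1.97 ± 0.19, the zinc finger gene ZBTB41 by 1.92 ± 0.13, SPRY4, a feedback inhibitor of growth factor signalling, by 1.58 ± 0.066, the kinetochore motor CENPE by 1.41 ± 0.14 and CCDC18 by 1.38 ± 0.16, all at 12 h. The cytokine LIF and CHAC1, which breaks down glutathione, both rose by 1.48 at 24 h (SE 0.10 and 0.089). The taste receptor gene TAS2R31 rose 2.63-fold at 8 h. At 12 h the log2 changes were -1.77 ± 0.23 for CDSN, -1.02 ± 0.11 for H4C14 and -1.01 ± 0.11 for MMP1. ID2, an inhibitor of DNA binding by helix-loop-helix factors, fell by 1.35 ± 0.089 at 24 h. SERPINB7 fell by 1.27 ± 0.13 and SPATA31G1 fell by 1.11 ± 0.12 at 24 h. Among small nuclear RNA genes, which were not tested as a class, the log2 changes were -1.51 ± 0.12 for RNVU1-15 at 24 h and, at 4 h, -1.12 ± 0.20 for RNU4ATAC, -1.04 ± 0.15 for RNVU1-3 and -1.01 ± 0.13 for RNVU1-6. The RNVU1 genes have near-identical copies. With a replicate block the time courses of RNU4ATAC, RNVU1-3 and RNVU1-6 had adjusted p = 0.0505, 0.0539 and 0.0715. By the naming rule, every array of the time point lay on the same side of every 0 h array.

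Genes of the ATF4 program rose together in H1299 at 24 h. Of the 30 measured ATF4 targets 25 rose and 0 fell (27 and 1, list alone), with a median change of 0.45 (adjusted p = 1.1e-29). Asparagine synthetase (ASNS) rose by 0.65 ± 0.062, STC2 by 0.93 ± 0.10 and the cystine transporter SLC7A11 by 1.30 ± 0.12. At 12 h 7 rose and 2 fell (7 and 3, list alone), with a median of -0.00086 (adjusted p = 0.782).

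Genes of G2 and mitosis rose in H1299 at 8 and 12 h. Of the 43 measured, at 8 h 30 rose and 0 fell (31 and 0, list alone). The list median was 0.26 (adjusted p = 8.54e-15, but 0.408 with estimated correlation). At 12 h 33 rose and 0 fell (37 and 1, list alone). The median was 0.36 (adjusted p = 1.33e-19, but 0.23 with estimated correlation). At 24 h 6 rose and 9 fell (8 and 11, list alone). The median was -0.14 (adjusted p = 0.013, but 0.767 with estimated correlation). That 24 h call ended with a replicate block (adjusted p = 0.215) and without 0 h replicate 5 (adjusted p = 0.0784). At 12 h the topoisomerase TOP2A rose by 0.85 ± 0.063, the mitotic kinesin KIF14 by 1.11 ± 0.10 and the kinetochore protein CENPF by 1.04 ± 0.093. Of the 43 genes of G1/S and replication, at 12 h 3 rose and 22 fell (3 and 23, list alone), with a median change of -0.25 (adjusted p = 1.33e-06, but adjusted p = 0.7 with estimated correlation). At 12 h the log2 changes were -0.74 ± 0.074 for the replication factor GINS2, -0.74 ± 0.065 for cyclin E1 (CCNE1) and -0.67 ± 0.066 for the flap endonuclease FEN1. Of the 43 replication-dependent histones, at 12 h 2 rose and 23 fell (2 and 25, list alone). The list median was -0.35 (adjusted p = 4.87e-07, but 0.7 with estimated correlation). Of the 32 measured genes of double-strand break repair, at 8 h 16 rose and 1 fell (17 and 2, list alone). The list median was 0.26 (adjusted p = 1.42e-05, but 0.7 with estimated correlation). The nuclease GEN1 rose by 0.78 ± 0.088 at 4 h and the polymerase POLQ by 0.65 ± 0.085 at 8 h. Of the 23 measured checkpoint genes, at 12 h 8 rose and 4 fell (8 and 6, list alone) and the list did not pass the test, with a median of 0.047 (adjusted p = 0.287). The checkpoint kinases ATM and ATR rose by 1.04 ± 0.11 and 0.78 ± 0.087 at 12 h.

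The p53 targets as a list did not pass the test at 2, 4, 8, 12 or 24 h in H1299 with the fixed settings. At 4 h 6 rose and 5 fell (9 and 5, list alone), with a median of 0.021 (adjusted p = 0.608), and at 24 h 9 rose and 3 fell (11 and 3, list alone), with a median of 0.13 (adjusted p = 0.0564). That 24 h median was 0.13 (adjusted p = 0.0247) with a replicate block. It was 0.12 (adjusted p = 0.0382) without 0 h replicate 4 and 0.14 (adjusted p = 0.0448) without 0 h replicate 6. Without 2 h replicate 1 it was 0.13 (adjusted p = 0.0492) and without 24 h replicate 2 0.11 (adjusted p = 0.0418). CDKN1A rose by 0.42 ± 0.071 at 24 h and MDM2 by 0.39 ± 0.059 at 12 h. GDF15, a stress-induced cytokine, rose by 1.17 ± 0.18 at 24 h and the apoptosome protein APAF1 by 0.74 ± 0.071 at 8 h, and GADD45A fell by 0.61 ± 0.059 at 12 h. Of the 26 measured immediate-early genes, at 2 h 2 rose and 10 fell (3 and 11, list alone), with a median change of -0.19 (adjusted p = 7.39e-06). The matricellular gene CCN1 fell by 0.98 ± 0.067 at 8 h, and the interferon-stimulated gene SAMD9 rose by 1.19 ± 0.14 at 12 h.

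In all, 6719 genes had a time course in H1299 (limma, 3659 with a rise and 3060 with a fall as their largest change), of which 88 rose and 13 fell by at least 2-fold. Against 0 h, 2542 genes changed at 2 h (1083 higher, 1459 lower). Those were 1491 and 1310 after quantile normalization and 1524 and 846 after median centring. At 4 h 2919 changed (1846 higher, 1073 lower). At 8 h 4524 genes changed (2769 and 1755) and at 12 h 5474 (3063 and 2411). At 24 h 2161 changed (1570 higher and 591 lower, but 1361 and 1101 after quantile normalization and 1114 and 746 after median centring). With array width in the model 4216 genes had a time course, and 4085, 2865 and 3263 changed at 2, 8 and 12 h. At 8 and 12 h every array was wider than any at 0 h, so the term cannot separate time from width. Without 1 array the 2 h count was 1577 or 1202 (2 h replicates 2 and 3), the 4 h count 1849 (4 h replicate 1), the 8 h count 2628 (8 h replicate 3). The 12 h count was 3137 (12 h replicate 2) and the 24 h count 1398 or 1293 (24 h replicates 1 and 3).

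**Figure D3:**
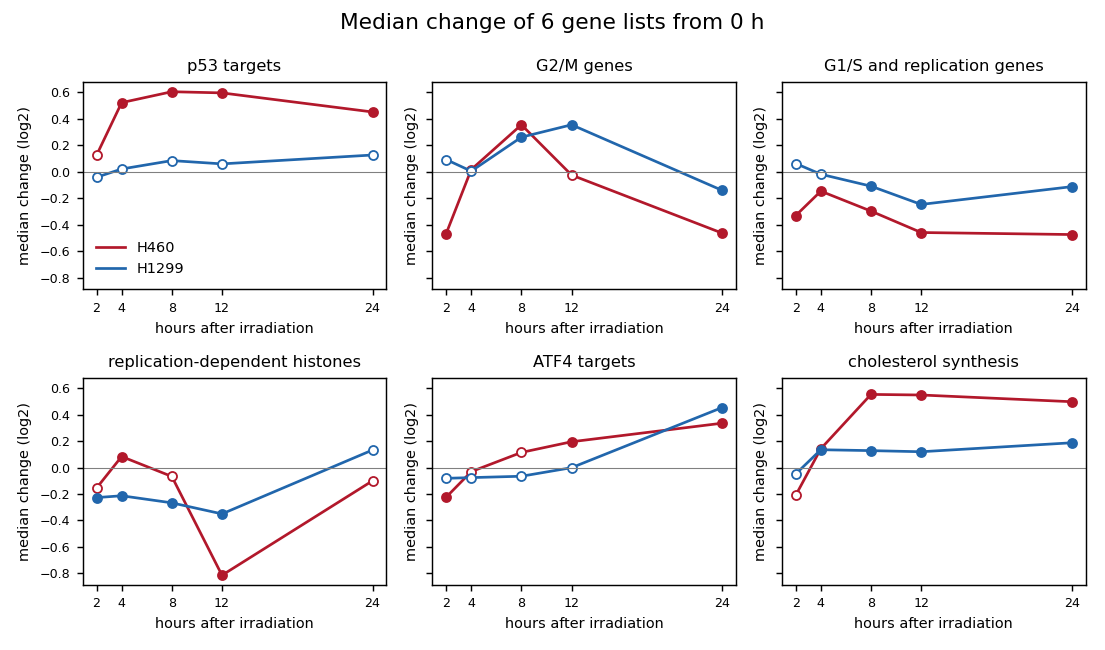
Median log2 change from 0 h (y axis) of 6 gene lists by hours after irradiation (x axis) in H460 and H1299. Filled points passed the list test at adjusted p under 0.05 with the preset correlation and open points did not. The p53 targets reach medians of 0.52 to 0.61 in H460 at 4, 8 and 12 h and stay between -0.041 and 0.13 in H1299.

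The difference between the lines was tested as the H460 change minus the H1299 change. With 1 line of each kind, a difference cannot be assigned to radiosensitivity. The p53 targets changed more in H460. Of the 44 measured, at 4 h 23 were higher and 0 lower (31 and 1, list alone), with a median difference of 0.55 (adjusted p = 5.61e-26). At 8 h 27 were higher and 0 lower (27 and 0, list alone), with a median difference of 0.59 (adjusted p = 2.95e-22). At 12 h 26 were higher and 1 lower (29 and 1, list alone), with a median difference of 0.52 (adjusted p = 2.37e-22). At 24 h 11 were higher and 1 lower (17 and 1, list alone), with a median difference of 0.27 (adjusted p = 3.78e-07). CDKN1A differed by 1.41 ± 0.15 and MDM2 by 0.82 ± 0.12 at 4 h. TP53INP1 differed by 1.60 ± 0.14 (1.76 in H460 and 0.16 in H1299) at 4 h, SPATA18 by 1.63 ± 0.18 (1.51 in H460 and -0.12 in H1299) at 12 h and DDB2, which recognises damaged DNA, by 1.08 ± 0.11 (0.86 in H460 and -0.22 in H1299) at 8 h. The stress-induced cytokine GDF15 differed by 1.75 ± 0.25 at 4 h.

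AMDHD1 had the largest difference of all genes that qualified for naming, 3.12 ± 0.16 at 24 h (adjusted p = 7.76e-18). At 24 h PLAC4 differed by 2.82 ± 0.22 (2.61 in H460 and -0.21 in H1299), PDK4 by 2.56 ± 0.19 (2.71 in H460 and 0.15 in H1299), SUCNR1 by 2.38 ± 0.22, SERPINB11 by 2.38 ± 0.23, SLC16A4 by 2.36 ± 0.21 and ABCA8 by 2.33 ± 0.22. DUSP1, a phosphatase that turns off MAP kinases, differed by 2.22 ± 0.12 (1.97 in H460 and -0.26 in H1299), the adhesion gene CHL1 by 2.19 ± 0.20 (2.10 in H460 and -0.092 in H1299) and the chloride channel family gene CLIC2 by 2.15 ± 0.25 (2.05 in H460 and -0.095 in H1299). ID2 differed by 2.12 ± 0.15, since it rose in H460 by 0.78 ± 0.11 and fell in H1299. In the other direction ZBTB41 differed by -1.74 ± 0.29 (-0.061 in H460 and 1.68 in H1299) at 8 h, the homeobox gene HOXB2 by -1.74 ± 0.21 (-0.99 in H460 and 0.75 in H1299) and MMP1 by -1.71 ± 0.18 (-1.76 in H460 and -0.048 in H1299) at 24 h. At 12 h JUN differed by -1.70 ± 0.16 (-1.73 in H460 and -0.032 in H1299), BLID by -1.63 ± 0.31 (0.33 in H460 and 1.97 in H1299) and DPY19L2P4 by -1.53 ± 0.23 (-0.49 in H460 and 1.04 in H1299). FAM111B differed by -1.57 ± 0.14 (-1.38 in H460 and 0.20 in H1299) and CCNE2 by -1.52 ± 0.19 (-1.79 in H460 and -0.27 in H1299) at 8 h. FHIP1A changed -1.25 in H460 and 0.25 in H1299 at 24 h, a difference with adjusted p = 0.00802. The time course difference of FHIP1A did not pass after quantile normalization (adjusted p = 0.112) or without H460 24 h replicate 1 or 2 or H1299 24 h replicate 2 or 3 (adjusted p = 0.0915, 0.0719, 0.149 or 0.0559). With a replicate block those of FHIP1A and CCNE2 had adjusted p = 0.0516 and 0.0693, and with ranks of time that of FHIP1A 0.0525.

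The genes of G2 and mitosis ended lower in H460 than in H1299, each relative to 0 h. Of the 43, at 12 h 0 were higher and 23 lower (0 and 32, list alone), with a median difference of -0.47 (adjusted p = 1.14e-20). At 24 h 0 were higher and 22 lower (0 and 31, list alone), with a median difference of -0.46 (adjusted p = 8.32e-14, but adjusted p = 0.148 with estimated correlation). The mitotic kinase AURKB and the proliferation marker MKI67 differed by -0.83 ± 0.11 (-0.98 in H460 and -0.15 in H1299) and -0.88 ± 0.16 (-0.54 in H460 and 0.34 in H1299) at 12 h. Of the 43 histones, at 12 h 0 were higher and 17 lower (0 and 22, list alone), with a median difference of -0.49 (adjusted p = 1.26e-14, but adjusted p = 0.148 with estimated correlation). Of the 22 genes of the cholesterol synthesis list, at 12 h 10 were higher and 0 lower (13 and 0, list alone), with a median difference of 0.44 (adjusted p = 1.2e-09). At 24 h 8 were higher and 0 lower (14 and 0, list alone), with a median difference of 0.41 (adjusted p = 2.18e-09). FADS2 differed by 1.32 ± 0.11 (1.53 in H460 and 0.22 in H1299) at 24 h. Of the 30 ATF4 targets, at 24 h 1 were higher and 8 lower (3 and 11, list alone), with a median difference of -0.24 (adjusted p = 0.0058, but adjusted p = 0.248 with estimated correlation), while SLC7A11 differed by -1.23 ± 0.17. The NF-kB inhibitor TNFAIP3 differed by 1.21 ± 0.12 (0.76 in H460 and -0.45 in H1299), and the antiviral gene IFIT2 by 1.72 ± 0.19, at 24 h. Of the 32 genes of double-strand break repair, at 2 h 2 were higher and 20 lower (2 and 22, list alone), with a median difference of -0.62 (adjusted p = 4.55e-08, but adjusted p = 0.248 with estimated correlation). With array width in the model that median was -0.28 (adjusted p = 0.00269).

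In all, the time course of 3072 genes differed between the lines (limma, 1880 with the largest difference positive and 1192 negative). With 1 mean per time point 8744 did (4142 and 4602), and with array weights 7137 (3473 and 3664). By time point, 5271 genes differed at 2 h (1872 higher and 3399 lower in H460, but 2583 and 2829 after quantile normalization). At 4 h 1572 differed (591 and 981, but 886 and 912 after quantile normalization and 975 and 638 after median centring). At 8 h 1861 differed (1207 and 654), at 12 h 1598 (959 and 639) and at 24 h 2291 (1426 and 865). Array weights gave 3121, 4200, 3883 and 4871 at 4, 8, 12 and 24 h. Of 100 splits of the arrays, the real one included, 3, 5 and 2 called as many at 8, 12 and 24 h, with up to 3598, 2797 and 2881 genes, so the 12 h count does not stand apart from them. With array width in the model the 2 h count was 1032. Without H460 2 h replicate 3 it was 2878. The 4 h count was 931, 964, 1018 or 1043 without H460 4 h replicate 2 or H1299 4 h replicate 1, 2 or 3. The 12 h count was 1065 without H460 12 h replicate 2 and the 24 h count 1509 without H460 24 h replicate 2. Of the genes with a time course, 3408 had one in both lines, against 2816 by chance. At 12 h 1394 genes rose in both (510 by chance) and 967 fell in both (406 by chance), while at 2 h 96 rose in both (181 by chance), 346 fell in both (346 by chance) and 688 fell in H460 and rose in H1299 (257 by chance), and 22 the reverse (243 by chance). These counts are without array width in the model. Across the 18404 genes, which are not independent replicates, the changes of the lines had r = -0.0015, 0.041, 0.38, 0.55 and 0.35 at 2, 4, 8, 12 and 24 h, and 0.1, 0.0097, 0.026, 0.26 and 0.21 with that term.

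The arrays at 0 h ask how the lines differed before irradiation (H1299 minus H460, 6 arrays each). TDRD12 and GTSF1, which act in the germline piRNA pathway, were higher in H1299 by 6.77 ± 0.12 and 6.11 ± 0.11, as were PLBD1 by 6.49 ± 0.13, the neuronal filament gene INA by 6.34 ± 0.15, the carboxypeptidase CPM by 6.17 ± 0.21 and the cancer-testis antigen MAGEA4 by 5.25 ± 0.14. ZNF542P, ZNF667-AS1, TSPYL5 and ZNF404 were higher in H1299 by 5.69 ± 0.12, 5.39 ± 0.16, 5.32 ± 0.087 and 5.23 ± 0.13. The aldo-keto reductase genes named by the rule had differences of -7.99 ± 0.10 for AKR1B10 (adjusted p = 1.24e-21), -7.37 ± 0.13 for AKR1C3 and -7.13 ± 0.091 for AKR1C1. The urea cycle enzyme CPS1 differed by -7.65 ± 0.091, the cadherin CDH11 by -7.35 ± 0.096, the kynureninase KYNU by -7.09 ± 0.11, the proteoglycan SRGN by -6.77 ± 0.11, TSPAN7 by -6.70 ± 0.10, the notochord factor TBXT by -6.55 ± 0.086 and ALDH1A1 by -6.44 ± 0.11. By the naming rule, no array of either line overlapped the other line. TDRD12 stood at 3.63 in H460, so differences of this size lack a measured floor.

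Of the 27 measured NRF2 targets, 0 were higher in H1299 and 27 lower (0 and 27, list alone), with a median difference of -1.67 (adjusted p = 1.91e-18). Of the 25 NF-kB targets, 5 were higher in H1299 and 18 lower (5 and 18, list alone), with a median difference of -0.86 (adjusted p = 0.000154). IL6 differed by -5.73 ± 0.14, CXCL8 by -5.77 ± 0.19, CXCL1 by -5.88 ± 0.22 and TNFAIP3 by -3.54 ± 0.075. Of the 37 interferon-stimulated genes, 5 were higher in H1299 and 22 lower (5 and 22, list alone), with a median difference of -0.37 (adjusted p = 0.00177, but adjusted p = 0.122 with estimated correlation), and OAS1 differed by -4.66 ± 0.14. Of the 43 histones, 27 were higher in H1299 and 6 lower (27 and 6, list alone), with a median difference of 0.59 (adjusted p = 0.00177, but adjusted p = 0.691 with estimated correlation). The keratin KRT19, the junction protein JUP and fibronectin (FN1) were lower in H1299, at -6.13 ± 0.11, -3.23 ± 0.098 and -4.77 ± 0.082, and N-cadherin (CDH2) and the receptor kinase AXL higher, by 3.78 ± 0.099 and 3.74 ± 0.078. The p53 targets had a median of -0.28 and did not pass the test (adjusted p = 0.152). In all, 10146 genes differed (limma, 5352 higher and 4794 lower in H1299), of which 1537 were at least 2-fold higher and 998 at least 2-fold lower.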

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

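In this part every test of array spread, of other splits of the arrays, of an early response and of time in culture was chosen only after the result was seen, and the test of blood cells was written before it.

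Among the 6 arrays of a line at 0 h, 1 array lay far from the others for 19 of 268 gene levels or array spreads, where 13.4 would be called by chance at about 1 in 20. Each value is given against the range of the other arrays, with the gap to the nearest as a share of the whole range in parentheses. For H460 0 h replicate 1 the values were CDC20 9.48 against 9.72 to 9.78 (0.786), MKI67 10.72 against 10.15 to 10.36 (0.63), RAD51AP1 7.61 against 8.05 to 8.21 (0.739) and OAS1 9.11 against 9.5 to 9.69 (0.672). With H460 0 h replicate 3 the values were TDRD12 4.03 against 3.45 to 3.63 (0.687). In H460 0 h replicate 6 the values were DUSP1 9.65 against 9.29 to 9.41 (0.645), CXCL1 12.48 against 12.04 to 12.19 (0.657) and TYROBP 5.62 against 6.17 to 6.36 (0.735). For H1299 0 h replicate 1 the values were BLID 5.36 against 4.32 to 4.69 (0.64) and RPS14 11.85 against 11.6 to 11.69 (0.626). At H1299 0 h replicate 2 the values were an array spread of 3.24 against 3.57 to 3.69 (0.743), RNVU1-15 7.64 against 7.96 to 8.09 (0.724), ZNF542P 9.1 against 9.4 to 9.48 (0.804), CCNG1 9.48 against 9.87 to 9.97 (0.784), CDC25A 8.06 against 8.46 to 8.66 (0.67), CCN1 9.99 against 10.22 to 10.33 (0.676), RPS29 4.94 against 6.1 to 6.49 (0.749) and TYROBP 6.37 against 5.67 to 5.77 (0.847). On H1299 0 h replicate 5 the values were FAM111B 8.33 against 7.91 to 8.05 (0.664).

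For 90 of 133 genes named by the fixed rule, the change from 0 h differed between the lines by a test of the difference itself, at the time point where the difference was largest. Many were named for a large change or difference, so this share is set by how they were named, and over all 18404 genes 3072 time courses differed. Values are the log2 change in H460 minus that in H1299. At 2 h the higher value was CHAC1 0.7959. At 2 h the lower value was STARD4 -1.018. Higher in H460 at 4 h were H4C14 1.049, CDKN1A 1.414, MDM2 0.8244, TP53INP1 1.599, GDF15 1.749 and GADD45A 1.001. Higher at 8 h were RNVU1-15 1.145, EDA2R 1.204, DDB2 1.081, GINS2 0.5516, RAD51C 1.075 and PER2 0.8534. Lower at 8 h were CCNE2 -1.521, ZBTB41 -1.737, TAS2R31 -1.398, FAM111B -1.572, TDRD12 -0.5962, E2F8 -0.9178 and UNG -0.7574. Above 0 at 12 h were DDIT4 0.7641, CPS1 0.7681, SPATA18 1.625 and SESN2 0.9844. Below 0 at 12 h were H2AC21 -1.259, JUN -1.703, H4C2 -1.005, BLID -1.631, SPRY4 -1.195, DPY19L2P4 -1.53, AURKB -0.8341, MKI67 -0.8784, TOP2A -0.6585, H4C1 -0.9387 and FOSL1 -1.225. Above 0 at 24 h were AMDHD1 3.116, PDK4 2.562, PLAC4 2.824, SUCNR1 2.381, ABCA8 2.334, CTH 1.819, SERPINB11 2.38, SLC16A4 2.357, VWA5A 1.955, LXN 1.931 and ID2 2.123. The 24 h differences also included SERPINB7 0.835, DUSP1 2.222, CHL1 2.193, CLIC2 2.149, ZNF542P 0.7076, AKR1B10 0.823, CDH11 0.6577, KYNU 0.7257, SRGN 0.6135, TBXT 0.656 and ALDH1A1 1.027. More genes higher at 24 h were CCNG1 0.8168, IL6 1.526, CCL20 1.498, IL1A 1.357, TNFAIP3 1.214, IFIT2 1.725, IFIT1 1.052, OAS1 0.9096, CCN1 1.633, CASP9 1.101 and ABCC3 0.6816. At 24 h the same held for JUP 0.8939, FN1 0.336, BNIP3L 1.235, SLC2A3 0.8589, FADS2 1.316, SCD 0.6885, DHCR7 0.7539, BHLHE40 0.755, LUM 1.119 and CD14 0.6574. Below 0 at 24 h were MMP1 -1.711, LIF -1.211, HOXB2 -1.736, FHIP1A -1.495, MAGEA4 -1.076, CDC20 -0.705, UBE2C -0.7396, CCNA2 -0.633, MCM5 -0.4698, SLC7A11 -1.229 and AXL -0.5055.

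For gene lists, 42 of 100 differences between the lines passed the test with the preset correlation, each list being tested at each time point. With an estimated correlation the calls held for p53 targets at 4, 8, 12 and 24 h, G2/M genes at 12 h and cholesterol synthesis at 12 and 24 h only. The others ended, with that adjusted p in parentheses after the median. Medians at 2 h were p53 targets 0.1658 (0.251), G2/M genes -0.4916 (0.248), G1/S genes -0.3684 (0.389), break repair -0.6213 (0.248), checkpoint genes -0.3991 (0.362), epithelial genes 0.2563 (0.533), hypoxia genes -0.1755 (0.386) and leukocyte markers 0.3146 (0.362). The 4 h medians were p53 targets 0.5532, G1/S genes -0.1388 (0.726), histones 0.313 (0.386), break repair -0.2809 (0.465) and ribosomal proteins 0.1705 (0.484). Those at 8 h were p53 targets 0.591, G1/S genes -0.1544 (0.514), break repair -0.196 (0.631), NRF2 targets 0.3017 (0.248), ATF4 targets 0.1526 (0.389), cholesterol synthesis 0.3776 (0.174) and ribosomal proteins 0.3475 (0.248). Medians at 12 h were p53 targets 0.5225, G2/M genes -0.4685, G1/S genes -0.1468 (0.465), histones -0.4858 (0.148), break repair -0.2535 (0.47), interferon genes 0.129 (0.251), NRF2 targets 0.2923 (0.145), ATF4 targets 0.1836 (0.243), cholesterol synthesis 0.4356 and ribosomal proteins 0.2342 (0.389). The 24 h medians were p53 targets 0.2743, G2/M genes -0.4596 (0.148), G1/S genes -0.3407 (0.248), histones -0.2482 (0.631), break repair -0.2124 (0.465), NF-kB targets 0.05537 (0.33), interferon genes 0.1778 (0.0938), NRF2 targets 0.2825 (0.155), ATF4 targets -0.2418 (0.248), hypoxia genes 0.1722 (0.33), cholesterol synthesis 0.4066 and ribosomal proteins 0.229 (0.47).

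Leaving out 1 array ended the call for p53 targets at 2 h, with adjusted p = 0.0581 without H460 0 h replicate 2, 0.0865 and 0.0508 without H460 2 h replicates 1 and 2. It also did for ATF4 targets at 8 h, with adjusted p = 0.0886, 0.0715 and 0.0509 without H460 0 h replicates 2, 5 and 6, 0.0597 and 0.051 without H460 8 h replicates 1 and 3, 0.0572, 0.0543, 0.0624 and 0.0533 without H1299 0 h replicates 1, 3, 4 and 6, 0.0519 and 0.068 without H1299 8 h replicates 1 and 2. The same held for epithelial genes at 2 h, with adjusted p = 0.0783 without H460 0 h replicate 6, 0.0508 and 0.0927 without H460 2 h replicates 2 and 3, 0.0651 without H1299 0 h replicate 2, 0.0609 and 0.0781 without H1299 2 h replicates 2 and 3. This was also so for G1/S genes at 4 h, with adjusted p = 0.103 without H460 0 h replicate 6, 0.0935 without H1299 0 h replicate 2. A call also ended for break repair at 8 h, with adjusted p = 0.0953 without H460 0 h replicate 6, 0.0732 without H1299 0 h replicate 2. So did that for hypoxia genes at 2 h, with adjusted p = 0.09 without H460 2 h replicate 3. Another ended for interferon genes at 12 h, with adjusted p = 0.0661 without H460 12 h replicate 2. The last ended for NF-kB targets at 24 h, with adjusted p = 0.0541 without H460 24 h replicate 2, 0.0706 without H1299 0 h replicate 2, 0.0586 without H1299 24 h replicate 3.

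The 7435 genes called at 2 h in H460 may reflect the narrow arrays of that time point, since r across genes between the change and the slope on array spread was -0.73 and 0 genes (limma, and 0 with its robust fit) were called with spread in the model, where 1528 had an unadjusted p under 0.05. That model cannot separate the 2, since the spreads of the 3 arrays do not overlap the others and the median standard error rose from 0.13 to 0.226. The leukocyte marker median of 0.336 was at percentile 93.4 of random sets matched on level (median 0.206, 95th percentile 0.348). This gave no sign of blood cells but cannot exclude them. An early response to irradiation could not be told from the rest, as 0 arrays were labelled unirradiated at 2 h.

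For the larger rise of p53 targets in H460 at 8 h, array spread was excluded as the whole cause, since the median difference with spread in the model was 0.5482 (adjusted p = 1.19e-20). A response to irradiation could account for it, and so could time in culture, which could not be told apart with 0 arrays labelled unirradiated after 0 h.

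For the rise of ATF4 targets in H1299 at 24 h, array spread was excluded as the whole cause, with a median of 0.4277 (adjusted p = 5.32e-28) with spread in the model. ATF4 targets respond to amino acid shortage, which may build up in culture, and with 0 arrays labelled unirradiated after 0 h, time in culture could not be told from a response to 2 Gy.

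Each comparison was rerun on splits of its arrays into groups of the same size. For the H460 time course 1 of 100 called as many genes, the real one (at most 4364 in another). For H460 at 2, 4, 8, 12 and 24 h it was 1 of 84 each (at most 5303, 223, 2335, 2812 and 2156). Of these 0, 80, 3, 1 and 3 differed more in spread, so width stays open at 2, 8, 12 and 24 h. In H1299 the time course had 1 of 100 (at most 1958). Each time point had 1 of 84 (at most 1764, 359, 684, 926 and 330). The difference of time courses had 1 of 100 (at most 97). By time point it was 1, 1, 3, 5 and 2 (at most 2812, 653, 3598, 2797 and 2881). For the lines at 0 h it was 1 of 100, but other splits mix the lines, so their 0 calls by limma tell little. At 8, 12 and 24 h the split with the most calls had differences in array spread of -0.499, -0.448 and -0.436, against 0.0698, 0.0945 and 0.212 in the real one.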

How the results depend on the processing

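The alternatives with array spread, those without the 4 narrow arrays, and the list tests after quantile normalization or median centring were chosen only after the data were seen, and the others were planned before. The cause of each change given here was not tested, except where fewer genes or arrays entered. All 19 counts of called genes stayed within 1.5 times the reported count with the filter on dim genes, with eBayes without trend, with robust eBayes and with median centring. The 3 time course counts also did with the square root of hours, the rank of the time point and the 24 h arrays left out.

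Counts of called genes moved by more than 1.5 times under these settings. With array spread as a covariate they were 2912 for the H460 time course, 0 for H460 2 h, 977 for H460 4 h, 132 for H460 8 h, 628 for H460 12 h, 1548 for H460 24 h, 4216 for the H1299 time course, 4085 for H1299 2 h, 2865 for H1299 8 h, 3263 for H1299 12 h and 1032 for the difference at 2 h. Those 0 calls are by limma, whose robust fit also gave 0, with 1528 at an unadjusted p under 0.05 (9039 without the term). With array weights the counts were 1797 for H460 4 h, 6979 for H460 8 h, 4230 for H1299 2 h, 7137 for the difference of time courses, 3121 for the difference at 4 h, 4200 for the difference at 8 h, 3883 for the difference at 12 h and 4871 for the difference at 24 h. With 1 mean per time point they were 12752 for the H460 time course and 8744 for the difference of time courses. With only the arrays of the 2 time points they were 207 for H460 4 h, 932 for H1299 2 h and 1233 for H1299 24 h. With all 42 arrays they were 1243 for H460 4 h, 4784 for H460 8 h, 1115 for H1299 2 h, 1730 for H1299 4 h and 1177 for H1299 24 h. With 0 h replicates 4 to 6 only they were 138 for H460 4 h, 903 for H460 8 h, 3544 for H460 12 h and 3145 for H460 24 h, and with replicates 1 to 3 only 1693 for H1299 2 h. Quantile normalization gave 1974 for H460 8 h, a replicate block 1552 for H1299 2 h and fitting all entries of the deposited file gave 833 for H460 4 h. Without the 4 narrow arrays the counts were 2535 for the difference at 12 h and 3732 for the difference at 24 h.

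With each array left out in turn, the counts ranged as follows: 6115 to 9256 for the H460 time course, 4349 to 8011 for H460 2 h, 138 to 845 for H460 4 h, 1071 to 4939 for H460 8 h, 3816 to 7408 for H460 12 h, 2820 to 6450 for H460 24 h, 5489 to 6846 for the H1299 time course, 1202 to 3482 for H1299 2 h, 1849 to 3245 for H1299 4 h, 2628 to 4514 for H1299 8 h, 3137 to 5498 for H1299 12 h, 1293 to 2408 for H1299 24 h, 2446 to 4174 for the difference of time courses, 2878 to 6601 for the difference at 2 h, 931 to 1846 for the difference at 4 h, 1257 to 2397 for the difference at 8 h, 1065 to 2141 for the difference at 12 h, 1509 to 3017 for the difference at 24 h, 9298 to 11377 for the lines at 0 h. A group left with 2 arrays is assumed to vary like the others.

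Arrays with the same number were no more alike than others within a line, with a mean r of residuals of -0.0091 in H460 and -0.019 in H1299 over 45 pairs each (6 and 11 pairs over 0.1). At 0 h between the lines the mean was 0.06 over 6 pairs (3 over 0.1).

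List medians are given with the adjusted p in parentheses, after a setting that ended a call, gave a new one or turned the median. Median centring left each list on its side of the threshold.

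An estimated correlation ended H460 calls at 2 h G2/M genes -0.47 (0.265), G1/S genes -0.33 (0.37), break repair -0.48 (0.305), checkpoint -0.31 (0.391), epithelial genes 0.23 (0.497), ATF4 targets -0.22 (0.385), hypoxia genes -0.21 (0.172), leukocyte markers 0.34 (0.211), at 4 h G1/S genes -0.15 (0.526), histones 0.083 (0.605), immediate-early genes -0.21 (0.305), NRF2 targets 0.059 (0.446), cholesterol synthesis 0.14 (0.211), at 8 h G2/M genes 0.36 (0.189), G1/S genes -0.30 (0.28), interferon genes 0.13 (0.361), NRF2 targets 0.30 (0.111), ribosomal genes 0.19 (0.432), at 12 h G1/S genes -0.46 (0.172), histones -0.81 (0.096), interferon genes 0.25 (0.172), NRF2 targets 0.31 (0.139), ATF4 targets 0.20 (0.287), hypoxia genes 0.20 (0.37), ribosomal genes 0.092 (0.716), at 24 h G2/M genes -0.46 (0.139), G1/S genes -0.47 (0.139), NF-kB targets 0.070 (0.385), interferon genes 0.36 (0.0743), NRF2 targets 0.35 (0.144), ATF4 targets 0.34 (0.0795), hypoxia genes 0.23 (0.211), ribosomal genes 0.24 (0.523). An estimated correlation ended H1299 calls at 2 h histones -0.23 (0.7), break repair 0.13 (0.767), ribosomal genes -0.17 (0.762), at 4 h histones -0.21 (0.762), break repair 0.23 (0.7), cholesterol synthesis 0.13 (0.7), ribosomal genes -0.17 (0.762), at 8 h G2/M genes 0.26 (0.408), G1/S genes -0.11 (0.767), histones -0.27 (0.762), break repair 0.26 (0.7), epithelial genes -0.16 (0.767), cholesterol synthesis 0.13 (0.7), ribosomal genes -0.14 (0.767), at 12 h G2/M genes 0.36 (0.23), G1/S genes -0.25 (0.7), histones -0.35 (0.7), break repair 0.27 (0.762), cholesterol synthesis 0.12 (0.762), ribosomal genes -0.15 (0.767), at 24 h G2/M genes -0.14 (0.767), G1/S genes -0.11 (0.762), cholesterol synthesis 0.19 (0.431). An estimated correlation ended difference calls (adjusted p above) at 2 h p53 targets 0.17, G2/M genes -0.49, G1/S genes -0.37, break repair -0.62, checkpoint -0.40, epithelial genes 0.26, hypoxia genes -0.18, leukocyte markers 0.31, at 4 h G1/S genes -0.14, histones 0.31, break repair -0.28, ribosomal genes 0.17, at 8 h G1/S genes -0.15, break repair -0.20, NRF2 targets 0.30, ATF4 targets 0.15, cholesterol synthesis 0.38, ribosomal genes 0.35, at 12 h G1/S genes -0.15, histones -0.49, break repair -0.25, interferon genes 0.13, NRF2 targets 0.29, ATF4 targets 0.18, ribosomal genes 0.23, at 24 h G2/M genes -0.46, G1/S genes -0.34, histones -0.25, break repair -0.21, NF-kB targets 0.055, interferon genes 0.18, NRF2 targets 0.28, ATF4 targets -0.24, hypoxia genes 0.17, ribosomal genes 0.23. An estimated correlation ended 0 h calls G1/S genes 0.32 (0.691), histones 0.59 (0.691), checkpoint 0.33 (0.691), interferon genes -0.37 (0.122), cholesterol synthesis 0.43 (0.691), ribosomal genes 0.25 (0.691).

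The spread term reversed the direction of H460 tests at 2 h G1/S genes 0.0013 (0.385), checkpoint 0.027 (0.431), NRF2 targets 0.17 (0.0161), epithelial genes -0.12 (0.0994), ribosomal genes 0.17 (0.000112), at 8 h break repair -0.14 (0.000983), checkpoint -0.080 (0.0208), at 12 h checkpoint -0.17 (0.0107), ribosomal genes -0.020 (0.801). The spread term reversed the difference medians at 2 h epithelial genes -0.090 (0.658). The spread term ended H460 calls at 2 h G2/M genes -0.050 (0.243), break repair -0.046 (0.972), ATF4 targets -0.091 (0.778), hypoxia genes -0.12 (0.128), leukocyte markers 0.068 (0.808), at 8 h interferon genes 0.024 (0.33), at 12 h ATF4 targets 0.080 (0.0994), hypoxia genes -0.0013 (0.358), at 24 h NF-kB targets -0.0081 (0.292), hypoxia genes 0.11 (0.063), ribosomal genes 0.10 (0.0716). The spread term ended H1299 calls at 8 h epithelial genes -0.012 (0.925), cholesterol synthesis 0.017 (0.317), at 12 h break repair 0.098 (0.464), cholesterol synthesis 0.045 (0.523). The spread term ended difference calls at 2 h G1/S genes -0.094 (0.711), checkpoint -0.093 (0.359), hypoxia genes -0.024 (0.348), leukocyte markers 0.057, at 4 h G1/S genes -0.078 (0.149), at 8 h ATF4 targets 0.13 (0.126), at 12 h interferon genes 0.11 (0.0759), at 24 h NF-kB targets 0.043 (0.052), hypoxia genes 0.15 (0.0826). The spread term ended 0 h calls G1/S genes 0.19 (0.419), checkpoint 0.26 (0.334), cholesterol synthesis 0.27 (0.293), ribosomal genes 0.080 (0.293). The spread term gave H460 calls at 2 h p53 targets 0.22 (2.9e-07), at 8 h histones -0.26 (1.03e-06), immediate-early genes -0.18 (0.0105), at 12 h G2/M genes -0.26 (1.75e-06), break repair -0.26 (1.16e-05), at 24 h histones -0.31 (0.000223), break repair -0.48 (2.2e-09), checkpoint -0.30 (0.000844). The spread term gave H1299 calls at 2 h G2/M genes 0.14 (0.00128), G1/S genes 0.10 (0.0363), checkpoint 0.14 (0.0187), at 24 h ribosomal genes -0.078 (0.00104). The spread term gave difference calls at 2 h histones 0.35 (7.98e-07), ribosomal genes 0.36 (1.92e-14), at 24 h checkpoint -0.22 (0.0108).

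Quantile normalization reversed the H460 medians at 12 h ribosomal genes -0.049 (0.653). Quantile normalization ended H460 calls at 2 h G1/S genes -0.14 (0.0853), checkpoint -0.087 (0.217), epithelial genes 0.085 (0.373), ATF4 targets -0.028 (0.653), hypoxia genes -0.099 (0.0949), leukocyte markers 0.13 (0.0933), at 4 h NRF2 targets 0.063 (0.0763), at 8 h ribosomal genes 0.044 (0.0997), at 12 h ATF4 targets 0.053 (0.311), hypoxia genes 0.069 (0.481), at 24 h NF-kB targets 0.14 (0.101), hypoxia genes 0.084 (0.102), ribosomal genes 0.053 (0.296). Quantile normalization ended H1299 calls at 8 h epithelial genes -0.11 (0.351), cholesterol synthesis 0.059 (0.12), at 12 h cholesterol synthesis 0.034 (0.287). Quantile normalization ended difference calls at 2 h G1/S genes -0.17 (0.0569), epithelial genes 0.16 (0.267), hypoxia genes -0.069 (0.25), leukocyte markers 0.16 (0.164), at 8 h ATF4 targets 0.068 (0.393), at 12 h ATF4 targets 0.10 (0.0657), at 24 h NF-kB targets 0.012 (0.0602), hypoxia genes 0.12 (0.145). Quantile normalization ended 0 h calls G1/S genes 0.19 (0.164), checkpoint 0.20 (0.0976), cholesterol synthesis 0.31 (0.0977). Quantile normalization gave H460 calls at 2 h p53 targets 0.30 (0.000102), interferon genes -0.21 (0.0298), at 8 h immediate-early genes -0.23 (0.000556), at 12 h G2/M genes -0.18 (0.00381), immediate-early genes -0.32 (0.0106), at 24 h break repair -0.31 (0.00053). Quantile normalization gave H1299 calls at 2 h G2/M genes 0.10 (0.00895), clock genes 0.077 (0.0134). Quantile normalization gave difference calls at 2 h interferon genes -0.11 (0.0289), ribosomal genes 0.20 (0.00791).

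Filtering dim genes ended H460 calls at 2 h checkpoint -0.31 (0.0808), epithelial genes 0.053 (0.197), ATF4 targets -0.22 (0.438), hypoxia genes -0.21 (0.0937), leukocyte markers 0.30 (0.202), at 8 h interferon genes 0.26 (0.0882), at 12 h ATF4 targets 0.20 (0.0882), hypoxia genes 0.20 (0.287), ribosomal genes 0.092 (0.341), at 24 h NF-kB targets 0.32 (0.165), hypoxia genes 0.23 (0.0961). Filtering dim genes ended H1299 calls at 8 h epithelial genes -0.20 (0.093), cholesterol synthesis 0.13 (0.0749), at 12 h break repair 0.27 (0.0533), cholesterol synthesis 0.12 (0.179). Filtering dim genes ended difference calls at 2 h epithelial genes 0.17 (0.21), hypoxia genes -0.18 (0.379), leukocyte markers 0.29 (0.397), at 4 h G1/S genes -0.14 (0.089), at 8 h ATF4 targets 0.15 (0.207), at 12 h interferon genes 0.16 (0.0705), at 24 h NF-kB targets 0.073 (0.153), hypoxia genes 0.19 (0.0952). Filtering dim genes ended 0 h calls G1/S genes 0.32 (0.184), checkpoint 0.33 (0.162), cholesterol synthesis 0.43 (0.162), ribosomal genes 0.25 (0.068). Filtering dim genes gave H460 calls at 2 h p53 targets 0.17 (0.000346), fibroblast markers 0.21 (0.0468), at 8 h histones -0.045 (0.0417), immediate-early genes -0.19 (0.00845), at 24 h break repair -0.19 (0.0115). Filtering dim genes gave H1299 calls at 2 h G2/M genes 0.093 (0.0443). Filtering dim genes gave difference calls at 2 h histones 0.14 (0.0238), ribosomal genes 0.21 (0.00142).

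The replicate block ended H460 calls at 2 h epithelial genes 0.23 (0.0592), at 4 h G1/S genes -0.12 (0.0507). The replicate block ended H1299 calls at 8 h G1/S genes -0.072 (0.211), at 24 h G2/M genes -0.10 (0.215). The replicate block ended difference calls at 2 h epithelial genes 0.25 (0.0543), at 8 h ATF4 targets 0.12 (0.118), at 12 h interferon genes 0.10 (0.063). The replicate block gave H460 calls at 2 h p53 targets 0.11 (0.0452), fibroblast markers 0.20 (0.0473), at 4 h ribosomal genes 0.069 (0.04), at 12 h epithelial genes -0.17 (0.0473). The replicate block gave H1299 calls at 2 h G2/M genes 0.14 (0.0066), checkpoint 0.14 (0.0263), at 4 h checkpoint 0.20 (0.0332), at 24 h p53 targets 0.13 (0.0247), break repair 0.13 (0.00497). The replicate block gave difference calls at 2 h ribosomal genes 0.20 (0.0234), at 4 h fibroblast markers 0.18 (0.0306).

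Camera on ranks ended H460 calls at 24 h NF-kB targets 0.070 (0.116). Camera on ranks ended difference calls at 8 h ATF4 targets 0.15 (0.0854), at 12 h interferon genes 0.13 (0.0769), at 24 h NF-kB targets 0.055 (0.439), hypoxia genes 0.17 (0.0557). Camera on ranks gave H1299 calls at 24 h break repair 0.085 (0.0315). Camera on ranks gave difference calls at 12 h hypoxia genes 0.16 (0.0366).

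Omitting narrow arrays ended H460 calls at 12 h ribosomal genes 0.092 (0.0631), at 24 h NF-kB targets 0.070 (0.0501). Omitting narrow arrays ended H1299 calls at 2 h break repair 0.091 (0.0973), at 8 h epithelial genes -0.11 (0.104), at 12 h cholesterol synthesis 0.070 (0.0547). Omitting narrow arrays ended difference calls at 24 h NF-kB targets 0.0053 (0.0924). Omitting narrow arrays gave H460 calls at 24 h break repair -0.20 (0.0209). Omitting narrow arrays gave H1299 calls at 24 h ribosomal genes -0.070 (0.00485). Omitting narrow arrays gave difference calls at 12 h hypoxia genes 0.19 (0.0109). Omitting narrow arrays gave 0 h calls G2/M genes 0.21 (0.03).

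With each array left out in turn, the list results that changed side of the threshold ranged as follows. H460 medians ran at 2 h p53 targets 0.070 to 0.15, histones -0.29 to -0.062, immediate-early genes -0.13 to 0.018, epithelial genes 0.13 to 0.31, ribosomal genes -0.13 to 0.026, at 4 h G1/S genes -0.20 to -0.094, histones -0.051 to 0.18, NRF2 targets 0.034 to 0.092, ribosomal genes -0.046 to 0.061, at 8 h histones -0.097 to -0.048, interferon genes 0.096 to 0.19, immediate-early genes -0.25 to -0.18, epithelial genes -0.15 to -0.089, at 12 h epithelial genes -0.21 to -0.15, hypoxia genes 0.11 to 0.23, ribosomal genes 0.075 to 0.13, at 24 h break repair -0.23 to -0.13, NF-kB targets 0.035 to 0.12. H1299 medians ran at 2 h G2/M genes 0.051 to 0.17, G1/S genes -0.030 to 0.12, break repair 0.064 to 0.18, checkpoint 0.082 to 0.16, clock genes 0.0015 to 0.062, at 8 h epithelial genes -0.23 to -0.081, at 12 h epithelial genes -0.22 to -0.11, cholesterol synthesis 0.070 to 0.14, at 24 h p53 targets 0.091 to 0.14, G2/M genes -0.17 to -0.11, histones 0.032 to 0.19, break repair 0.048 to 0.12, ribosomal genes -0.070 to 0.0083. Medians of the difference ran at 2 h p53 targets 0.12 to 0.19, epithelial genes 0.14 to 0.34, hypoxia genes -0.19 to -0.095, ribosomal genes 0.072 to 0.25, at 4 h G1/S genes -0.19 to -0.082, immediate-early genes -0.22 to -0.075, fibroblast markers 0.13 to 0.22, at 8 h break repair -0.23 to -0.15, ATF4 targets 0.13 to 0.22, at 12 h interferon genes 0.089 to 0.17, hypoxia genes 0.13 to 0.20, at 24 h NF-kB targets 0.0053 to 0.14. Medians before irradiation ran G2/M genes 0.12 to 0.21.

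Of the named genes, TYROBP in H460 at 2 h changed sign to -0.14 and MARVELD3 in H1299 at 12 h to 0.054 with array spread as a covariate. With the same direction, calls of named genes ended for 21 with array spread, 17 with a replicate block, 14 after quantile normalization, 14 with the square root of hours, 9 without the 24 h arrays, 6 with ranks of time, 6 with 1 mean per time point, 3 with median centring, 3 without trend, 3 without the narrow arrays, 2 with array weights and 2 with robust eBayes. With 1 array left out, 171 results of named genes lost the call and 8844 kept it.

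All entries of the table were not run for single genes, since a gene has 1 entry in each fit. Without the narrow arrays no value exists for H460 at 2 h or for the difference at 2 h, and without the 24 h arrays none for genes named at 24 h. The values came without background levels, which limits what can be said of dim genes.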

Other observations

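No test in this part was chosen after its result was seen, except array width in the model and the list tests after quantile normalization. Genes of the response to low oxygen moved in H460. Of the 27 measured hypoxia genes, at 24 h 11 rose and 3 fell (12 and 3, list alone), with a median change of 0.23 (adjusted p = 0.0054, but adjusted p = 0.211 with estimated correlation). BNIP3L, a mitophagy receptor, rose by 1.14 ± 0.12 and the glucose transporter SLC2A3 by 1.23 ± 0.12 at 24 h. At 12 h the median was 0.20 (adjusted p = 0.0401, but adjusted p = 0.37 with estimated correlation), and at 2 h -0.21 (adjusted p = 0.0018, but adjusted p = 0.172 with estimated correlation). At 2, 12 and 24 h the median was -0.12 (adjusted p = 0.128), -0.0013 (adjusted p = 0.358) and 0.11 (adjusted p = 0.063) with array width in the model, -0.099 (adjusted p = 0.0949), 0.069 (adjusted p = 0.481) and 0.084 (adjusted p = 0.102) after quantile normalization. Without dim genes the adjusted p was 0.0937, 0.287 and 0.0961, and at 12 h without replicate 1 or 2 it was 0.0636 or 0.0745.

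Of the 42 measured genes of cytosolic ribosomal proteins, in H460 at 8 h 12 rose and 0 fell (13 and 0, list alone), with a median change of 0.19 (adjusted p = 1.75e-06, but adjusted p = 0.432 with estimated correlation), and 0.044 (adjusted p = 0.0997) after quantile normalization. In H1299 at 8 h 0 rose and 11 fell (0 and 12, list alone), with a median change of -0.14 (adjusted p = 0.00026, but adjusted p = 0.767 with estimated correlation), and the median difference was 0.35 (adjusted p = 6.13e-13, but adjusted p = 0.248 with estimated correlation). Circadian clock genes (19 measured) passed at no time point with the fixed settings, with 0.033 (adjusted p = 0.0573) at 2 h in H1299, and 0.077 (adjusted p = 0.0134) after quantile normalization, and the list passed with adjusted p = 0.0432 without H1299 0 h replicate 3, 0.0342 and 0.049 without H1299 2 h replicates 2 and 3.

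Of the 14 measured leukocyte markers in H460 at 2 h, 7 rose and 0 fell (8 and 0, list alone), with a median change of 0.34 (adjusted p = 0.000706, but adjusted p = 0.211 with estimated correlation), and with array width in the model the median was 0.068 (adjusted p = 0.808). It did not pass after quantile normalization (adjusted p = 0.0933) or without dim genes (adjusted p = 0.202). Fibroblast markers (15 measured) passed at no time point in either line with the fixed settings. At 2 h in H460 the median was 0.21 (adjusted p = 0.0699), but adjusted p = 0.0473 with a replicate block and 0.0468 without dim genes. Of the 27 epithelial genes in H460 at 2 h, 7 rose and 0 fell (5 and 0, list alone), with a median change of 0.23 (adjusted p = 0.0412, but adjusted p = 0.497 with estimated correlation), and in H1299 at 8 h 0 rose and 4 fell (0 and 0, list alone), with a median change of -0.16 (adjusted p = 0.0374, but adjusted p = 0.767 with estimated correlation). The H460 median was -0.12 (adjusted p = 0.0994) with array width in the model, and the H1299 one -0.012 (adjusted p = 0.925). After quantile normalization adjusted p was 0.373 and 0.351, and without dim genes 0.197 and 0.093. With a replicate block the H460 one was 0.0592. Leaving out 1 array the H460 call ended with adjusted p = 0.077 without H460 0 h replicate 6, 0.0628 and 0.122 without H460 2 h replicates 2 and 3, and the H1299 one with adjusted p = 0.104 without H1299 0 h replicate 2, 0.0659 and 0.0771 without H1299 8 h replicates 2 and 3. Mesenchymal genes (29 measured) were not called in any comparison, and at 0 h their median was 0.067 and their mean -0.12. For the lists called with the fixed settings the median, the mean and the test had the same sign. Checkpoint genes in H460 at 2 h had a median of -0.31 (adjusted p = 0.00155, but adjusted p = 0.391 with estimated correlation), 0.027 (adjusted p = 0.431) with array width in the model, -0.087 (adjusted p = 0.217) after quantile normalization, and adjusted p = 0.0808 without dim genes.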
